A study of Mus musculus with 6 samples.

How the data were processed

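The 6 libraries used hold nuclei from whole mouse adrenal glands, each from 1 pair of glands per the labels' protocols, made with a droplet-based 3' protocol. The deposited values are UMI counts per gene and barcode, made with Cell Ranger, per the submitters' processing notes, which also name Seurat and the mm10 build. Cell Ranger 4.0.0 is named in the headers of KO replicate 1 and WT replicate 1, whose files list 32285 genes, and 3.1.0 in those of the other libraries, whose files list 31053, per the file headers. Whether intronic reads were counted, and how reads shared between genes were handled, is not given in the sources used here. The deposited barcodes had been filtered before deposit, since the lowest count per barcode lay between 500 and 511 UMIs. The 30406 genes in both annotations were used.

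The groups were taken from the labels alone. For 1 library the title says WT and the genotype field says KO, so it was left unassigned, took part in the clustering and was left out of every test except the alternatives that count it as KO or as WT. Replicate numbers follow the order of the accessions. The gene annotation was used as a batch term, since each annotation holds both genotypes. The deleted part of Tmem127 is not given in the labels, so its level was reported and used to judge no label. The design, the tests, the gene lists and the rule for named genes were fixed before the data were examined.

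Barcodes with fewer than 300 genes or at least 5% mitochondrial UMIs were removed, 48 of 21724 in all. Doublets were scored per library with scrublet in scanpy, and in each library the highest scores were marked up to the share expected at 0.8% per 1000 barcodes. This marked 685 barcodes, 88 and 75 in KO replicates 1 and 2, 182, 105 and 115 in WT replicates 1, 2 and 3, and 120 in the unassigned library, while the automatic threshold would have marked 514. They were removed, which left 20991 nuclei: 3225 and 2793 in KO, 4467, 3272 and 3525 in WT and 3709 in the unassigned library. Simulated doublets catch pairs of unlike nuclei, and pairs of the same type stay in.

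All 6 libraries were embedded together (2000 variable genes, 30 principal components, correction for library by the Harmony algorithm written in numpy), joined to 20 neighbours and clustered by the Leiden method at resolution 0.8 into 26 clusters, without use of genotype. A cluster took a name when at least 3 markers of a list had a log2 fold of at least 1 over the other nuclei and a share of at least 10%. Leading genes were held against 1 name only: macrophage was refused where the dendritic cell genes Flt3 or Clec9a were among them. The 18 marker lists covered chromaffin cells, zona fasciculata, zona glomerulosa, X-zone, capsule or fibroblasts, endothelium, macrophages, T or NK cells, B or plasma cells, Schwann or sustentacular cells, pericytes or smooth muscle, adipocytes, ganglion neurons, mesothelium, hepatocytes, kidney tubule, skeletal muscle and erythroid cells. Clusters 3, 7 and 22 stayed unnamed. The zona glomerulosa-like class joined clusters 2 and 4. Cluster 2 (2165 nuclei) had 11 markers that passed. Cluster 4 (1629 nuclei) had 3, the fewest allowed, and 0 among its 10 leading genes. Names end in "-like" because they rest on markers alone.

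Counts were summed per library and class, and classes with at least 20 nuclei in each of the 5 grouped libraries were tested. Genes were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, TMM factors, filterByExpr) with terms for batch and genotype and Benjamini-Hochberg adjustment at 0.05, two-sided. Genes were named by a rule: Tmem127, then the 10 with the largest positive and the 10 with the largest negative fold among genes that passed and moved the same way in both batches. If fewer than 10 passed, the 10 smallest p-values were named as values. Members of the fixed lists were named beside their list. Some genes that the rule names are not reported here. The 19 gene lists covered catecholamines, secretory granules, the RET receptor complex and sympathoadrenal transcription factors, MAPK output, lysosome and autophagy, endosomal sorting, the ATF4 response, cholesterol synthesis, steroid hormone synthesis, hypoxia, oxidative phosphorylation, insulin and FOXO targets, glucocorticoid receptor targets, immediate early genes and heat shock, proliferation, interferon response, WNT and hedgehog genes, genes near Tmem127 and mitochondrial transcripts. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Shares of nuclei were compared by an exact two-sided permutation test of the logit share, whose smallest p is 0.1. Shares of nuclei with Pnmt, or with Mki67 or Top2a, were taken after each nucleus was thinned to 1000 UMIs, and nuclei with fewer were left out, 3 and 36 chromaffin-like nuclei in KO replicates 1 and 2 and 4, 6 and 1 in WT. Of all nuclei this left out 62 of 3225 and 968 of 2793 in KO and 85 of 4467, 697 of 3272 and 117 of 3525 in WT. Of macrophage-like nuclei it left out 3 of 128 and 62 of 109 in KO and 8 of 167, 54 of 104 and 10 of 178 in WT.

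Depth differed between libraries: chromaffin-like nuclei summed to 2480158 and 694590 UMIs in KO, 4403746, 953384 and 1942656 in WT and 2993746 in the unassigned library. Tmem127 therefore rested on 94 and 32 UMIs there in KO and 120, 22 and 51 in WT. The pipeline was tested on simulated data with the same depths and 200 changed genes per class. It recovered 45%, 35%, 15% and 55% of 2-fold changes and 87%, 79%, 74% and 85% of 4-fold changes in all nuclei, chromaffin-like, zona fasciculata-like and zona glomerulosa-like nuclei, with 0 false of 132 calls, 5 of 119, 4 of 93 and 5 of 145. With the spread simulated gene by gene, 18 of 140, 12 of 126, 7 of 89 and 9 of 149 calls were false.

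Alternatives were the unassigned library counted as KO or as WT, no batch term, DESeq2, DESeq2 size factors in edgeR, no filter on low counts, predicted doublets kept, nuclei with at least 1000 genes only, each library left out, the libraries of the second annotation alone, and a coarser (0.3) and a finer (1.6) clustering. Shares of nuclei were also compared with edgeR's quasi-likelihood test of nuclei per class and library, with the batch as a term. Chosen after the data were seen were a test of the difference in genotype effect between classes (edgeR, library as a block), other spread estimates in edgeR, all nuclei without hepatocyte-like nuclei, chromaffin-like nuclei without 1 small cluster, and other splits of the libraries. Gene positions are those of GENCODE M21 on mm10. Raw reads were not used here, so deletion of Tmem127 exons was not checked. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.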

Results

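Nuclei from the adrenal glands of female C57BL/6J mice, 10 to 11 months old, were sorted on the DNA stain DAPI and sequenced as droplet-based 3' RNA libraries, in which each captured RNA molecule carries a unique molecular identifier (UMI). The mice were wild type (WT) or knockout (KO) for Tmem127, which encodes a transmembrane protein of the endosomal and lysosomal system and is a tumour suppressor gene of human phaeochromocytoma, the tumour of adrenal chromaffin cells. The labels place 2 libraries in the KO group and 3 in the WT group. A sixth library carries contradictory labels, a title that says WT and a genotype field that says KO, and its values are given only as those of an unassigned library. Each library is 1 sample, and the files hold 21724 barcodes in all. KO replicate 1 had 21650324 UMIs over 3317 barcodes, with a median of 5419 per barcode, and KO replicate 2 had 4825169 over 2886, with a median of 1289. WT replicate 1 had 43377724 UMIs over 4653 barcodes (median 7675), WT replicate 2 had 8294105 over 3393 (median 1783) and WT replicate 3 had 19319589 over 3642 (median 4114.5). The unassigned library had 21994492 UMIs over 3833 barcodes (median 4434). KO replicate 1 and WT replicate 1 were counted against 1 gene annotation and the other libraries against another, so both annotation batches hold KO and WT libraries. Levels are in CPM, the UMIs of a gene scaled to the summed UMIs of the nuclei named, with the SD between libraries. A fold is the log2 fold change of KO against WT with the batch as a term, with its standard error (SE).

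Tmem127 RNA was not lower in the libraries labelled KO when all nuclei were summed. In all nuclei it stood at 45.9 and 45.3 CPM in the KO libraries, against 38.1, 38.1 and 36.1 in the WT libraries and 36.4 in the unassigned library. In chromaffin-like nuclei the KO libraries had 37.9 (exact 95% Poisson interval 30.6 to 46.4) and 46.1 (31.5 to 65.0) CPM, and the WT libraries had 27.2 (22.6 to 32.6), 23.1 (14.5 to 34.9) and 26.3 (19.55 to 34.5). The fold was 0.23 ± 0.14 (SE) in all nuclei, 0.64 ± 0.24 in chromaffin-like, 0.34 ± 0.27 in zona fasciculata-like and 0.18 ± 0.18 in zona glomerulosa-like nuclei, with n = 2 KO and 3 WT libraries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these 4 values was 0.751, 0.923, 0.999 and 0.733. Among the other classes that measured it, the fold was below 0 in adipocyte-like (-0.23 ± 0.61) and endothelial-like nuclei (-0.16 ± 0.27) and above 0 in the rest. The gene (ENSMUSG00000034850) lies on chromosome 2 from 127247908 to 127261107, plus strand, in mm10, and its last exon, exon 4, from 127256957 to 127261107, holds 3846 bases of 3' untranslated region. The labels do not say which part of the gene is deleted. Where the tags of Tmem127 fall was not measured, since raw reads were not used. If they fall mostly in that last exon, as 3' tags can, they can lie outside the deleted part. The level of Tmem127 therefore checks no label. KO therefore stands below for the libraries labelled KO. The genes beside Tmem127 gave folds within their error: Ciao1, a cytosolic iron-sulfur assembly factor, had -0.19 ± 0.24 and Snrnp200, a spliceosomal helicase, had 0.06 ± 0.16 in all nuclei.

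**Figure D1:**
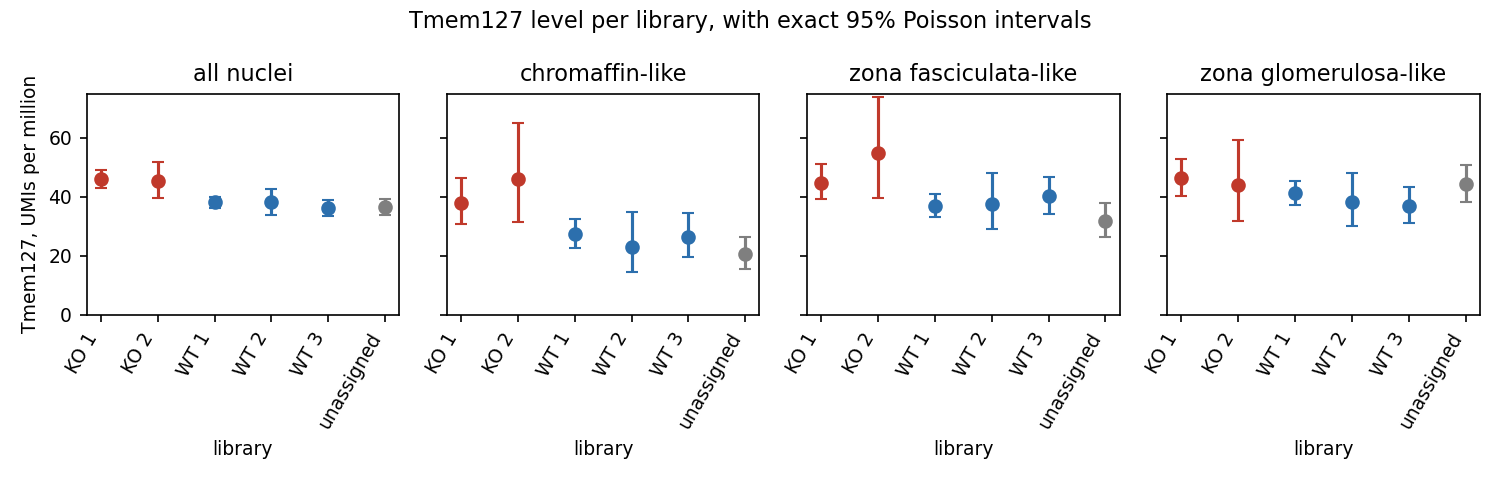
Tmem127 level (CPM) in each of the 6 libraries, in all nuclei and in 3 adrenal cell classes, with exact 95% Poisson intervals that cover counting error only. In all nuclei the KO libraries stand at 45.9 and 45.3 and the WT libraries between 36.1 and 38.1.

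Chromaffin-like nuclei took a mean of 8.33% ± 1.17 (SD, n = 2) of the nuclei in the KO libraries and 6.02% ± 0.880 (SD, n = 3) in the WT libraries. Per library the share was 7.50% and 9.17% in KO and 6.34%, 6.69% and 5.02% in WT, and within each annotation batch the KO library lay above the WT libraries. An exact two-sided permutation test of the logit share gave p = 0.1, the smallest that 2 against 3 libraries allow over 10 splits, so this test cannot reach 0.05. By edgeR's quasi-likelihood test of nuclei per class, with the batch as a term and Benjamini-Hochberg adjustment, the log2 fold was 0.47 (adjusted p = 0.226). No class passed that test, and the smallest adjusted p was 0.0605, for mesothelial-like nuclei. Cortical classes took alike shares: zona glomerulosa-like nuclei, named from the aldosterone-producing outer zone, 18.3% ± 1.34 in KO and 18.2% ± 2.25 in WT (exact permutation p = 1), and zona fasciculata-like nuclei, named from the corticosterone-producing zone, 15.7% ± 2.09 and 15.0% ± 1.42 (p = 0.6, same test). Endothelial-like nuclei took 18.1% ± 4.86 in KO and 23.4% ± 2.55 in WT (p = 0.2), capsule or fibroblast-like nuclei 15.7% ± 8.29 and 11.4% ± 4.60 (p = 0.5) and macrophage-like nuclei 3.94% ± 0.0469 and 3.99% ± 0.960 (p = 1), all by exact permutation. That test leaves out the batch. Within each batch capsule or fibroblast-like nuclei also lay higher in KO (9.83% against 6.74%, and 21.55% against 11.49% and 15.94%), and endothelial-like nuclei lay lower. By edgeR's quasi-likelihood test with the batch as a term, their log2 folds were 0.61 (adjusted p = 0.181) and -0.45 (adjusted p = 0.226). Unnamed cluster 22, led by Wdfy4, Clec9a and Flt3, took 0.414% ± 0.0285 in KO and 0.721% ± 0.0915 in WT (exact permutation p = 0.1). The 9 other classes and numbered clusters gave exact permutation p-values from 0.3 to 0.9. The sort and the UMI minimum of the deposited barcodes can set such shares.

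Pnmt, the enzyme that turns noradrenaline into adrenaline, had at least 1 UMI in 24.6% ± 14.1 (SD, n = 2) of KO and 28.4% ± 9.54 (SD, n = 3) of WT chromaffin-like nuclei after every nucleus was thinned to 1000 UMIs (exact permutation p = 0.6). The shares split by annotation batch: 14.6% in KO replicate 1 and 17.6% in WT replicate 1, against 34.5% in KO replicate 2 and 35.7% and 31.8% in WT replicates 2 and 3. Thinned zona fasciculata-like nuclei, which should lack Pnmt, had it in 0.361%, 0.304%, 5.78%, 3.17% and 0.620% in the same order of libraries. Before thinning the chromaffin-like shares were 54.5%, 53.7%, 49.2%, 51.6% and 69.5%, at median depths of 9367, 15124, 2314.5, 3643 and 10259 UMIs. The corresponding depths of the zona fasciculata-like nuclei were 8389, 13540, 1701, 2609 and 7382 UMIs. Mki67 or Top2a, genes of the cell cycle, had a UMI in 0.350% ± 0.0477 of thinned KO nuclei and 0.359% ± 0.0960 of thinned WT nuclei of all classes (exact permutation p = 0.9). Before thinning they had one in 1.09% and 0.465% of KO and 0.963%, 0.581% and 0.965% of WT nuclei, shares that depth affects. In thinned macrophage-like nuclei the share was 2.93% ± 1.88 in KO, from 2 of 125 and 2 of 47 nuclei, and 0 in each WT library (exact permutation p = 0.1). Before thinning it was 2.34% and 1.83% in KO and 1.20%, 0% and 0.562% in WT. Thinned zona glomerulosa-like nuclei had 0.334% ± 0.244 in KO and 0.710% ± 0.440 in WT (exact permutation p = 0.5). The permutation p lay between 0.3 and 0.9 in chromaffin-like, zona fasciculata-like, endothelial-like, capsule or fibroblast-like and pericyte or smooth muscle-like nuclei and in clusters 3 and 7.

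**Figure D2:**
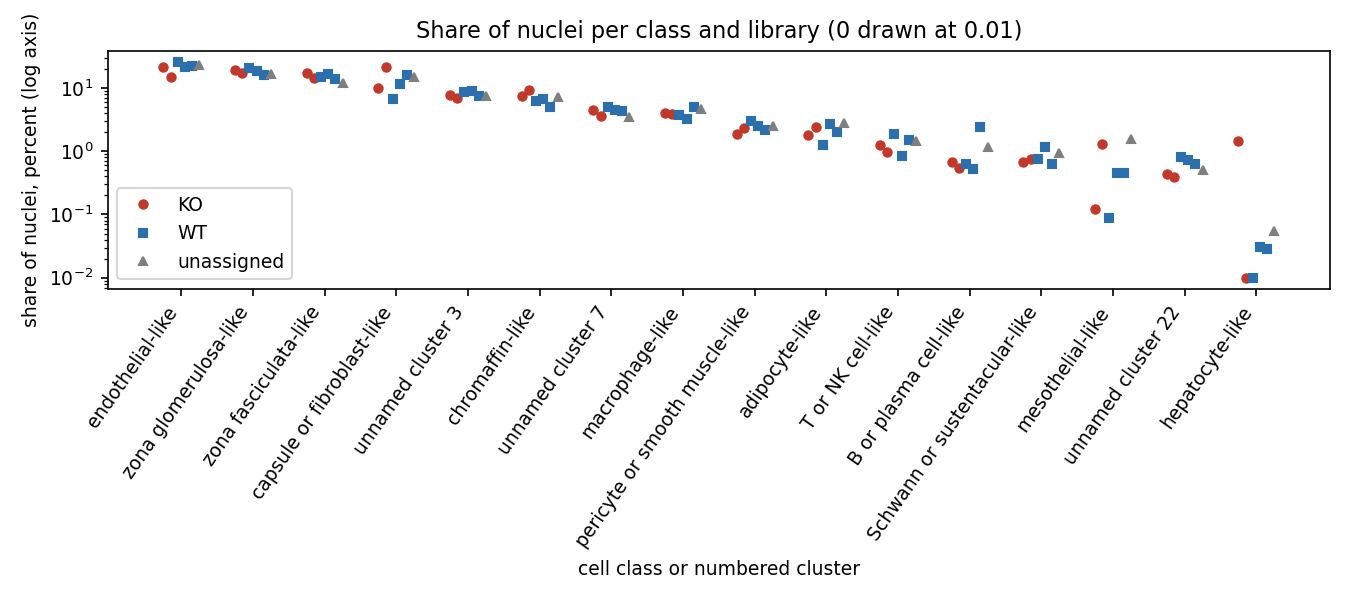
Share of nuclei (percent, log axis, 0 drawn at 0.01) in each cell class or numbered cluster, 1 point per library. The KO libraries lie above the WT libraries for chromaffin-like nuclei (7.50% and 9.17% against 5.02% to 6.69%).

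In zona glomerulosa-like nuclei edgeR's quasi-likelihood test called 50 of 11713 genes between KO and WT, of which 24 were higher and 26 lower in KO. WT replicates 1 and 3 against the rest, a split that mixes the genotypes, gave 47 calls. The count alone therefore does not tie these genes to the genotype. Of the 50, 0 stayed called with the unassigned library counted as KO and 4 with it counted as WT. The class includes cluster 4, which met the naming rule with only 3 markers. Pde10a, a phosphodiesterase that breaks down cAMP and cGMP, fell from 783 ± 308 CPM (SD, n = 3) in WT to 131 ± 0.0224 (SD, n = 2) in KO, a fold of -2.58 ± 0.27 (SE). Npr3, the clearance receptor of natriuretic peptides, fell from 10.1 ± 4.29 to 1.45 ± 0.853, a fold of -3.46 ± 0.62. The call of Npr3 was lost with DESeq2, with doublets kept, among nuclei with at least 1000 genes and without the batch term. It was also lost without WT replicate 1 and with the unassigned library counted as KO or as WT. It held with DESeq2 size factors in edgeR, without the filter, without WT replicate 2 or 3 and with coarser or finer clusters. Hsd3b6, the 3-beta-hydroxysteroid dehydrogenase isoform of aldosterone-producing cells, fell from 49.2 ± 7.66 to 22.9 ± 4.87, a fold of -1.17 ± 0.19. Ppp2r2b, a regulatory subunit of protein phosphatase 2A, fell from 602 ± 146 to 179 ± 50, a fold of -1.66 ± 0.21. The adjusted p of these 4 genes was 0.000914, 0.0266, 0.0168 and 0.00379 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

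The other genes with the largest falls in zona glomerulosa-like nuclei were Acvr1c, the activin receptor ALK7 (fold -1.54 ± 0.29), Fam19a2, a secreted chemokine-like protein (-1.32 ± 0.25), and Mthfd1l, a mitochondrial folate enzyme (-1.27 ± 0.19). They were followed by Phtf2 (-1.24 ± 0.15), Synpo2, an actin-binding protein (-1.16 ± 0.21), and Lin7a, a scaffold protein of cell junctions (-1.07 ± 0.16). Acvr1c turned to a fold of 0.48 when the unassigned library was counted as KO. The largest rises were those of H2-Q10, a class Ib histocompatibility gene (4.13 ± 0.68, from 0.614 ± 0.392 to 7.82 ± 2.36 CPM), Npas2, a clock transcription factor (2.91 ± 0.45, from 2.40 ± 0.827 to 14.8 ± 5.00), and Asic2, an acid-sensing sodium channel (2.17 ± 0.24, from 33.6 ± 16.3 to 138 ± 36.3). Also among them were Il31ra, a cytokine receptor (2.24 ± 0.42), Shank2, a postsynaptic scaffold (1.99 ± 0.38), and Plin1, a lipid droplet protein (1.72 ± 0.29). Gm19951 and Gm48099, annotated as non-coding, and Gm15564, annotated as antisense, rose with folds of 2.42 ± 0.40, 2.42 ± 0.43 and 1.79 ± 0.35. Adjusted p for these genes ran from 0.00102 (Asic2) to 0.0407 (Gm15564) among the rises and from 0.00253 (Phtf2) to 0.0344 (Fam19a2) among the falls (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The effect here minus that in zona fasciculata-like nuclei was -0.26 ± 0.46 for Gm48099, 0.09 ± 0.36 for Gm19951 and -0.04 ± 0.35 for Gm15564. It was 0.09 ± 0.29 for Il31ra and 0.23 ± 1.17 for H2-Q10, so these rises were not shown to be particular to this class. For Npas2, Asic2, Shank2 and Plin1 it was 2.56 ± 0.67, 1.59 ± 0.33, 2.57 ± 0.39 and 1.42 ± 0.44, though no gene passed that test. H2-Q10, H2-K1 and Hsd3b6 have close paralogs, and how reads shared between paralogs or overlapping strands were counted is not given in the sources used here. Of 50 hepatocyte-like nuclei, 46 were in KO replicate 1, and hepatocyte RNA as a source of H2-Q10 here was not tested. Pde10a lies on chromosome 17 from 8525372 to 8986648 and Npr3 on chromosome 15 from 11839896 to 11907287 (mm10). Hsd3b6 lies on chromosome 3 from 98805504 to 98814443, Ppp2r2b on chromosome 18 from 42637432 to 43059471 and Asic2 on chromosome 11 from 80880169 to 81968457 (mm10).

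All 50 genes moved the same way in both annotation batches, a property that the rule for naming genes asked of its 20 genes. Other cell types' markers and a sign of RNA composition moved with the groups in these nuclei. Gm42418, a transcript within the ribosomal RNA locus, was at 14893 and 11653 CPM in KO and 5776, 7147 and 3565 in WT. The summed zona glomerulosa markers, which include the called genes Hsd3b6 and Vsnl1, were lower in both KO libraries (7266 ± 228 against 7977 ± 505 CPM). The summed markers of zona fasciculata (6452 ± 148 against 5570 ± 321), chromaffin cells (410 ± 38.7 against 335 ± 43.9) and adipocytes, which include Plin1 (34.0 ± 7.59 against 17.4 ± 5.50), were higher. Chance alone separates 2 libraries from 3 in 2 of 10 splits. None of the 19 gene lists passed the camera test with preset correlation in zona glomerulosa-like nuclei. The smallest adjusted p was 0.0624, for proliferation (median fold -0.71, 15 members) and interferon response (0.38, 12 members). The 35 measured lysosome and autophagy genes had a median fold of 0.02, and among 17 genes of steroid hormone synthesis only Hsd3b6 passed over all genes. Star, the cholesterol import protein, had a fold of 0.34 ± 0.18 and Cyp11a1, the first enzyme of the pathway, 0.21 ± 0.17. The steroid list had a median fold of 0.20. DESeq2 called 41 genes, 37 of them among the 50. Of the genes named above it did not call Npr3, Acvr1c, H2-Q10, Npas2, Il31ra, Shank2, Gm19951, Gm48099 and Gm42418, though all 50 kept their sign. The count depends on the handling of the libraries: edgeR called 0 genes with the unassigned library counted as KO, 4 with it counted as WT, 0 without the batch term and 65 to 116 with 1 library left out.

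**Figure D3:**
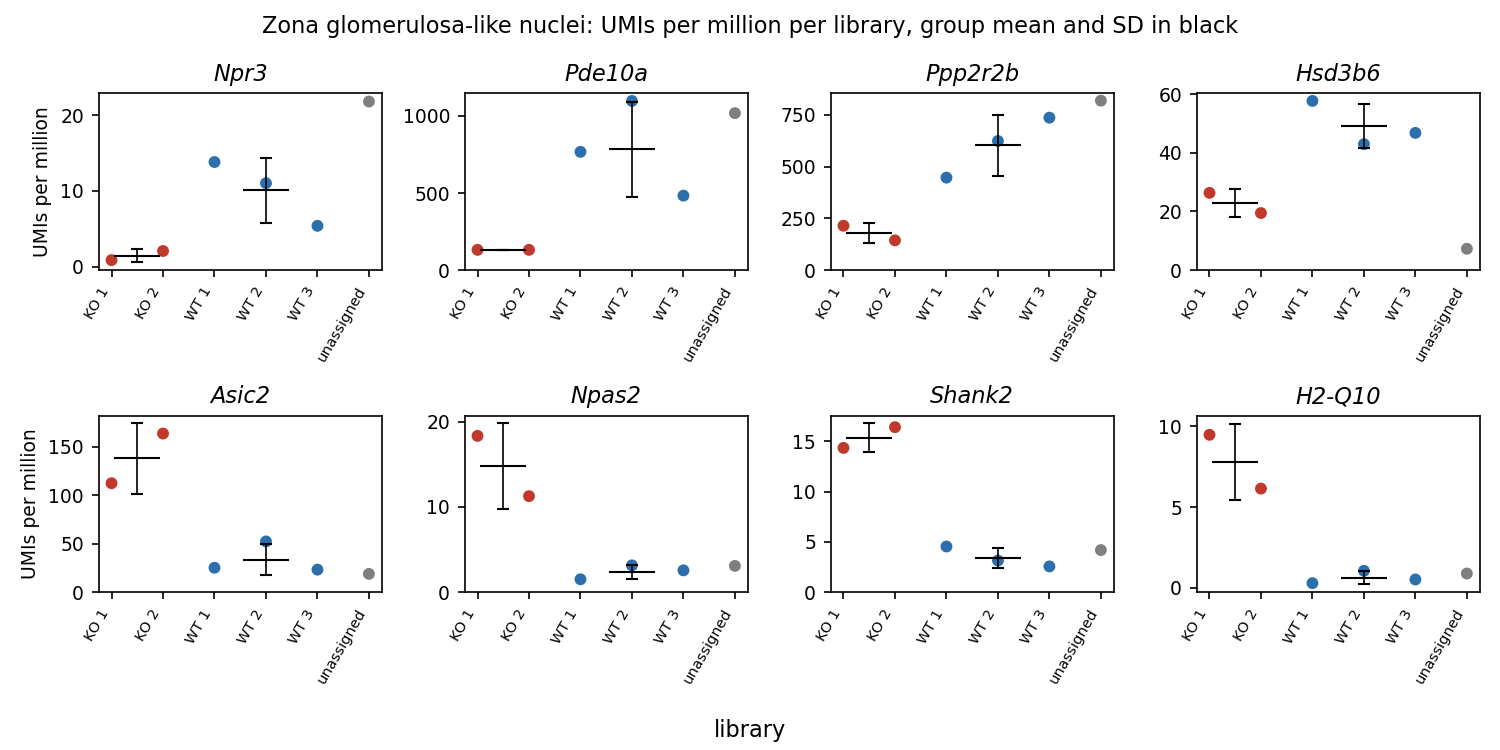
Levels (CPM) of 8 genes in zona glomerulosa-like nuclei, 1 point per library, with the mean and SD of the KO (n = 2) and WT (n = 3) libraries in black. Npr3, Pde10a, Ppp2r2b and Hsd3b6 are lower in both KO libraries than in every WT library, and Asic2, Npas2, Shank2 and H2-Q10 are higher.

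In chromaffin-like nuclei, the cells from which phaeochromocytoma arises, immediate early genes stood higher in KO as a group. Their list with heat shock genes had a median fold of 1.47 over 13 members, 12 of them above 0. Of these, 9 passed when adjusted over the list alone. Fos, an AP-1 transcription factor, stood at 97.7 ± 28.7 CPM (SD, n = 2) in KO and 11.5 ± 8.25 (SD, n = 3) in WT, a fold of 2.79 ± 0.40 (SE). Junb, its partner, stood at 42.9 ± 1.55 and 8.55 ± 0.918 (2.25 ± 0.28), and Egr1, a growth factor-responsive transcription factor, at 290 ± 201 and 75.6 ± 15.4 (1.85 ± 0.28). The list passed camera with preset correlation (adjusted p = 2.69e-11) and did not hold with an estimated one (adjusted p = 0.502 with an estimated correlation). The sum of the list was 446 and 1333 CPM in the KO libraries and 207, 370 and 255 in the WT libraries. In the unassigned library it lay between those of the KO libraries, though its level of Fos lay below both. Were that library WT, KO replicate 1 would not lie above every WT library in this sum. In the same nuclei the summed markers of Schwann or sustentacular cells (5686 ± 16.1 against 6148 ± 390 CPM) and of ganglion neurons (1480 ± 0.495 against 1765 ± 36.4) were lower in both KO libraries than in every WT library, and those of capsule or fibroblasts (76.1 ± 8.42 against 52.7 ± 3.66) and Gm42418 (12281 and 9722 against 5371, 5539 and 2709) were higher.

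No single gene passed in chromaffin-like nuclei: edgeR's quasi-likelihood test called 0 of 11024 genes, 577 had an unadjusted p under 0.05, and DESeq2 called 9. The 10 smallest p-values, given as values and not as changes, included beside Fos, Junb and Egr1 the phosphatase gene Dusp1 (fold 2.04 ± 0.33), with 32.0 ± 13.8 CPM in KO and 7.58 ± 1.58 in WT. They also included Caln1, a calcium-binding protein (1.29 ± 0.22), Bmpr1b, a BMP receptor (-1.36 ± 0.19), Gpc6, a glypican (-0.99 ± 0.17), and the non-coding Gm26917 (1.10 ± 0.18) and Gm48099 (2.82 ± 0.50). Their adjusted p lay between 0.149 (Junb) and 0.224 (Gm48099) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Catecholamine genes lay near their WT levels: Th, the first enzyme of the pathway, had a fold of 0.04 ± 0.16 and Ddc, the aromatic amino acid decarboxylase, -0.29 ± 0.16. Chga and Chgb, granins of the secretory granule, had -0.02 ± 0.15 and 0.19 ± 0.27, and Ret, the receptor tyrosine kinase of the sympathoadrenal lineage, had 0.45 ± 0.58 at 5.99 ± 2.36 CPM in KO.

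Camera with preset correlation passed 4 further lists in chromaffin-like nuclei, all toward higher levels in KO. Glucocorticoid receptor targets had a median fold of 0.46 (11 of 11 members above 0, adjusted p = 0.000614), of which Mt1, a metallothionein, had 1.24 ± 0.32 and Fkbp5, a chaperone of the receptor, 0.14 ± 0.15. Mitochondrially encoded transcripts had 1.35 (adjusted p = 0.00312), interferon response 0.34 (adjusted p = 0.0246) and WNT and hedgehog genes of cortical renewal 0.34 (adjusted p = 0.0246). None of the 4 held with an estimated correlation: adjusted p = 0.502, 0.632, 0.623 and 0.623 with an estimated correlation. The lists that did not pass were those of catecholamines (median fold 0.14), secretory granules (-0.02), the RET receptor complex and sympathoadrenal transcription factors (0.24), MAPK output (0.05), lysosome and autophagy (0.13), endosomal sorting (-0.13), the ATF4 response (0.11), cholesterol synthesis (0.11) and steroid hormone synthesis (0.16). Nor did those of hypoxia (0.02), oxidative phosphorylation (0.01), insulin and FOXO targets (0.09), proliferation (0.26) and the genes near Tmem127 (0.30), with camera adjusted p from 0.0651 (MAPK output) to 0.936 (cholesterol synthesis). The mean fold was 0.10 for the secretory granule list, opposite in sign to its median. Mitochondrial transcripts were high in KO replicate 2 alone (2398 CPM in all nuclei, against 421 in KO replicate 1 and 522 to 918 in WT). Without KO replicate 2 their median fold in chromaffin-like nuclei was -0.43 and 1 list passed, that of immediate early genes. With 1 library left out, edgeR called 8 to 101 genes.

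**Figure D4:**
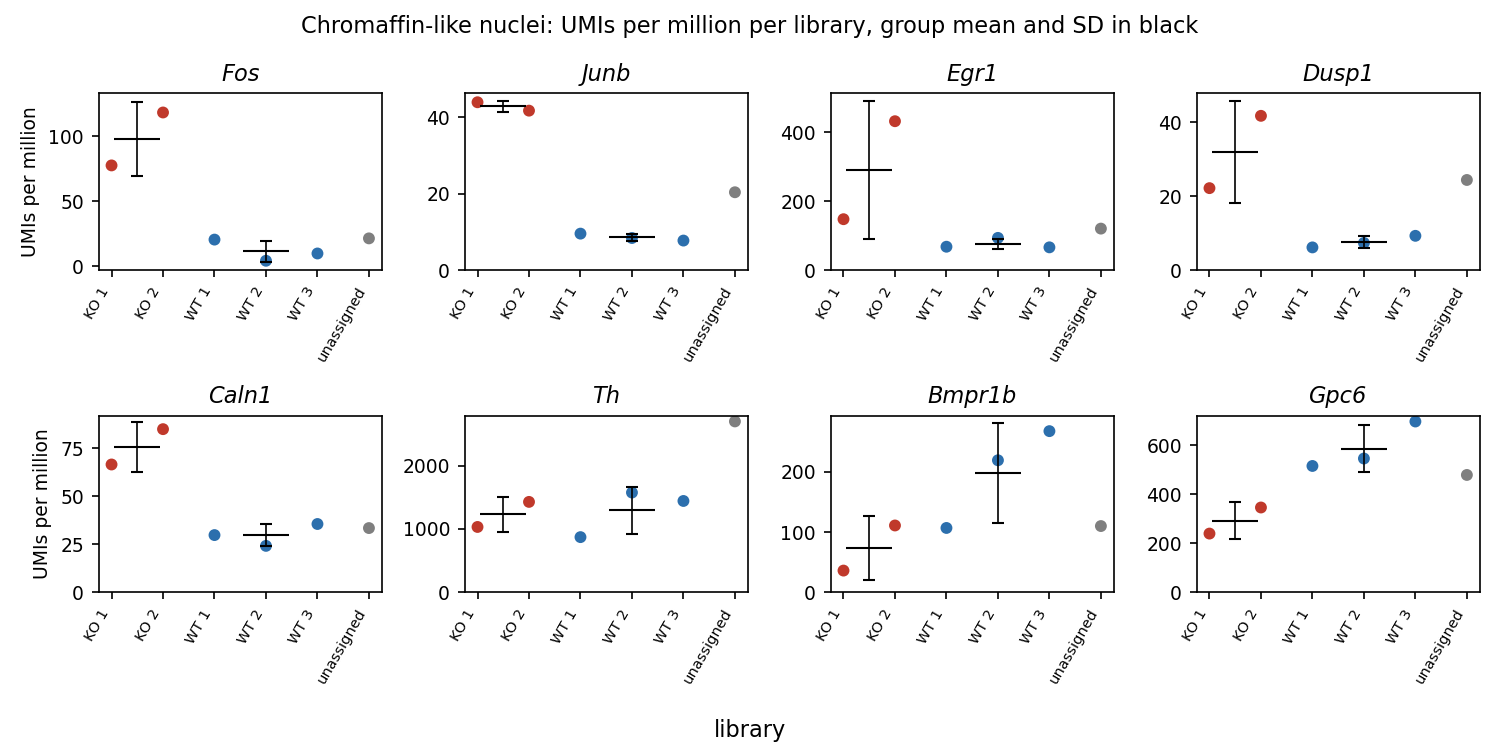
Levels (CPM) of 8 genes in chromaffin-like nuclei, 1 point per library, with the mean and SD of the KO (n = 2) and WT (n = 3) libraries in black. Fos and Junb stand above every WT library in both KO libraries, and Th (fold 0.04 ± 0.16) overlaps.

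In zona fasciculata-like nuclei edgeR's quasi-likelihood test called 0 of 11999 genes, with 264 at an unadjusted p under 0.05, and DESeq2 called 4. The smallest p-values, given as values, belonged to genes that were higher in KO: Gm48099 (fold 2.75 ± 0.43), Ptp4a1, a protein tyrosine phosphatase (2.35 ± 0.38), Cmss1 (1.70 ± 0.34), Taco1, a mitochondrial translation activator (1.36 ± 0.27), and H2-Q10 (4.07 ± 0.85). They also included Camk1d, a calmodulin-dependent kinase (1.35 ± 0.29), Acaa1b, a peroxisomal thiolase (4.67 ± 1.04), and H2-K1 (1.14 ± 0.27). Gcgr, the glucagon receptor, had 30 UMIs in the KO libraries and 0 in WT, at least 26.5-fold higher against a floor of 3 counts over the WT group. This bound pools the KO libraries, which held 4912634 UMIs of this class in replicate 1 and 784541 in replicate 2. It does not show a rise in each. The adjusted p was 0.790 for Gm48099, 0.910 for Ptp4a1 and 0.999 for the others (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Ptp4a1 had 0 UMIs in both libraries of the first annotation batch, and 121 CPM in KO replicate 2 against 24.6 and 21.3 in WT replicates 2 and 3. Steroid genes lay within their error: Star had -0.33 ± 0.34 and Cyp11a1 -0.34 ± 0.39, and the steroid list had a median fold of -0.09. Camera with preset correlation passed 8 lists toward higher levels in KO: secretory granules (median fold 0.46), the RET receptor complex and sympathoadrenal transcription factors (1.14, 5 members), MAPK output (0.32) and glucocorticoid receptor targets (0.25). Also passed were immediate early genes and heat shock (0.46), interferon response (0.19), WNT and hedgehog genes (0.22) and mitochondrial transcripts (0.52). With preset correlation their adjusted p ran from 0.00472 to 0.0400, and all 8 were lost, at adjusted p = 0.727 with an estimated correlation. Without KO replicate 2 camera's direction turned for 4 of them, with medians of -0.27 for MAPK output, -0.51 for mitochondrial transcripts, 0.092 for interferon response and 0.19 for immediate early genes. Then 3 lists passed, against 0 without WT replicate 3. Hepatocyte markers were at 37.5 and 15.3 CPM in the KO libraries and 0.856, 14.1 and 2.73 in WT, and Gm42418 at 16372 and 15753 against 7045, 8433 and 3936. With 1 library left out, edgeR called 2 to 46 genes.

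When all nuclei of a library were summed, edgeR's quasi-likelihood test called 0 of 16571 genes, with 1136 at an unadjusted p under 0.05, and DESeq2 called 59. The smallest p-values, as values, were those of Slc38a3, an amino acid transporter (25.04 and 0.872 CPM in KO, 0.0848 ± 0.0734 in WT), H2-Q10 (fold 3.58 ± 0.38), Hnf4aos, annotated as antisense (4.95 ± 0.59), and Gcgr (3.42 ± 0.45). Next came Thrsp, a regulator of lipogenesis (1.33 ± 0.16), S100a8, a neutrophil protein (0.0491 and 116 CPM in KO, 0.619 ± 0.462 in WT, so that KO replicate 2 alone carries it), Gata4, a transcription factor (1.19 ± 0.16), and Zfp385b (1.77 ± 0.23). Ppp2r2b had -0.95 ± 0.13 and Tnc, an extracellular matrix protein, -0.97 ± 0.14. Adjusted p of these 10 genes lay between 0.166 and 0.207 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Gata4 was a leading gene of cluster 5, a capsule or fibroblast-like cluster. It held 140 of 3225 and 401 of 2793 nuclei in KO and 97 of 4467, 185 of 3272 and 277 of 3525 in WT. The share of such a cluster can move a fold in summed nuclei, which was not tested. Of 50 hepatocyte-like nuclei, 46 were in KO replicate 1, where hepatocyte markers were at 294 CPM, against 50.1 in KO replicate 2 and 7.71 to 30.7 in WT. Without these nuclei edgeR called 0 genes, with 1068 at an unadjusted p under 0.05. Hepatocyte RNA as a source of the rises of H2-Q10, Slc38a3, Hnf4aos, Gcgr and Acaa1b, here or in single classes, was not tested. Camera with preset correlation passed 5 lists toward higher levels in KO: secretory granules (median fold 0.29, adjusted p = 0.0132), the RET receptor complex and sympathoadrenal transcription factors (0.45, adjusted p = 0.00335), immediate early genes and heat shock (0.68, adjusted p = 0.0027), interferon response (0.21, adjusted p = 0.0278) and mitochondrial transcripts (0.71, adjusted p = 0.0167). None held: adjusted p = 0.879 with an estimated correlation for the RET and immediate early lists and adjusted p = 0.91 with an estimated correlation for the other lists. Without KO replicate 2 camera's direction turned for mitochondrial transcripts (median -0.49) and interferon response (0.035). Of the 18 marker lists, those of zona glomerulosa (2420 ± 81.0 against 2886 ± 77.5 CPM) were lower in both KO libraries than in every WT library. Those of hepatocytes, kidney tubule (4.75 ± 4.99 against 0.969 ± 0.276) and skeletal muscle (14.3 ± 1.69 against 11.1 ± 1.30) were higher, and the other 14 overlapped. With 1 library left out, edgeR called 6 to 207 genes.

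The 9 other classes and clusters with enough nuclei gave 50 calls in all by edgeR's quasi-likelihood test. In T or NK cell-like nuclei 30 of 2994 genes passed, 27 of them lower in KO, among them Plcb1, a phospholipase C (fold -2.59 ± 0.46, from 1618 to 241 CPM), Frmd5 (-2.90 ± 0.50), and Scarb1, the receptor for high-density lipoprotein (-1.90 ± 0.47). Markers of zona fasciculata in these nuclei were at 980 and 1230 CPM in KO and 1987, 3816 and 1372 in WT. In adipocyte-like nuclei 16 of 6719 genes passed, 12 higher in KO, among them St3gal6, a sialyltransferase (1.99 ± 0.28), H2-Q10 (2.32 ± 0.35) and Acaa1b (2.46 ± 0.44), and 4 lower, among them Tshr, the thyrotropin receptor (-2.09 ± 0.38). Egr1 was also called there (4.42 ± 0.69), on KO replicate 2 alone: it stood at 307 CPM in that library, 26.8 and 5.78 in WT replicates 2 and 3, and 0 in KO replicate 1 and WT replicate 1. Taco1 was the single call in endothelial-like nuclei (1.51 ± 0.18, adjusted p = 0.0169 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Chn2, a protein that regulates Rac (-1.94 ± 0.31), the single call in macrophage-like nuclei. Capsule or fibroblast-like nuclei had 2 calls, Gm48099 (2.39 ± 0.33) and Kctd8, an auxiliary subunit of GABA-B receptors (-1.77 ± 0.25). Adjusted p ran from 0.00723 to 0.0493 in T or NK cell-like and from 0.0374 to 0.0384 in adipocyte-like nuclei (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Schwann or sustentacular-like nuclei, pericyte or smooth muscle-like nuclei and unnamed clusters 3 and 7 had 0, with 95, 153, 458 and 240 genes at an unadjusted p under 0.05, and DESeq2 called 0, 0, 3 and 0. The genes named in these classes, outside the rule for named genes, were chosen after their values were seen.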

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

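The tests of genotype effects between classes, of the Gm42418 transcripts, of the T or NK cell genes, of immediate early genes in other classes and of other library splits were all chosen after the results they concern were seen.

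A test of the difference between classes set apart a pair of genes. For Asic2 the genotype effect in chromaffin-like nuclei minus that in zona glomerulosa-like nuclei was -2.16 ± 0.28 (SE) on the log2 scale, and for Ppp2r2b it was 1.71 ± 0.22, each with adjusted p = 0.00397 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In chromaffin-like nuclei Asic2 stood at 1577 CPM in KO and 1528 in WT, and Ppp2r2b at 267 and 275. No gene passed this test between zona glomerulosa-like and zona fasciculata-like nuclei, where 262 of 11158 had an unadjusted p under 0.05 (edgeR), nor between chromaffin-like and zona fasciculata-like nuclei, where 253 of 10130 did. Mesothelial-like nuclei, of the layer that covers the gland, took 1.54% of the unassigned library, which the main comparisons leave out, against 0.124% and 1.33% in KO and 0.0895%, 0.458% and 0.454% in WT.

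Immediate early genes and heat shock genes stood higher in KO chromaffin-like nuclei (median fold 1.47). A small cluster of 52 chromaffin-like nuclei, led by Asxl3, Nkain2 and Fos, held 28 from KO replicate 2, and without it the median fold was 1.53, so this cluster does not account for the pattern. Handling of whole KO glands could raise these genes in every class: 0 of the 9 other classes that the list was tested in, T or NK cell-like and Schwann or sustentacular-like nuclei not among them, had a median below 0, and in 2 of the 9 both KO libraries stood above every WT library, which does not decide it. Camera with preset correlation passed the list in 6 of the 9, with medians up to 1.22 in macrophage-like and 1.07 in adipocyte-like nuclei, and all 6 were lost, from adjusted p = 0.615 with an estimated correlation to 0.926, and the median over 3 genes in pericyte or smooth muscle-like nuclei was 1.503. The genotype is the biological alternative, and this design cannot separate it from handling. The unassigned library, whose labels contradict each other, also had a sum of the list above every WT library in chromaffin-like nuclei.

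Gm42418, Gm26917, Cmss1, Camk1d and Taco1 rose in KO zona glomerulosa-like nuclei, and Gm42418 lies in the ribosomal RNA locus. A property of the whole KO libraries, such as their RNA or preparation, could raise them in every class, and the lowest class median of their fold was 0.88, above the 0.5 set for this test. That fits a property of the libraries and does not exclude an effect of the genotype in every cell type. The unassigned library had 3230 CPM of Gm42418 in all nuclei, against 12478 and 15251 in KO and 3821 to 7750 in WT.

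Of the genes called in T or NK cell-like nuclei, 27 were lower in KO. RNA of cortical cells in these nuclei, free or from droplets that held both, may account for them: 27 of the 27 had a higher WT level in cortical nuclei, against 36.5% of all 2994 genes tested. If the KO libraries as a whole held less free cortical RNA, these genes could fall in other classes too. Their median fold was 0.02 ± 0.11 (SE) in macrophage-like nuclei (12 of 27 below 0) and 0.002 ± 0.077 in endothelial-like nuclei (12 of 24). In capsule or fibroblast-like nuclei it was -0.16 ± 0.07 (21 of 24), against -2.44 ± 0.13 in T or NK cell-like nuclei. No fall of that size was therefore seen in these other classes. Because the genes were chosen for their fall in T or NK cell-like nuclei, a smaller shortage of free cortical RNA is not excluded. No biological explanation was tested for this pattern.

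Other splits of the 5 libraries into 2 and 3 were fitted in the same way. In zona glomerulosa-like nuclei 1 of the 9 splits gave as many calls, the real one with 50, and the highest other, WT replicates 1 and 3 against the rest, gave 47. In T or NK cell-like nuclei 2 of the splits gave as many as the real 30, with 55 for the highest other, and in adipocyte-like nuclei 1 did, the real one with 16, against 15. So few splits allow no share under 0.05.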

How the results depend on the processing

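The permutation tests of class and marker shares allow no p under 0.05, so their side of the threshold could not change. In edgeR's quasi-likelihood test of nuclei per class, with Benjamini-Hochberg adjustment, mesothelial-like nuclei had adjusted p = 0.0605, and 0.0142 with the unassigned library as KO and 0.623 with it as WT. Tmem127 passed under no alternative. Its fold ran from 0.17 to 0.30 in all nuclei, 0.37 to 0.87 in chromaffin-like, 0.20 to 0.51 in zona fasciculata-like and 0.11 to 0.24 in zona glomerulosa-like nuclei. In endothelial-like nuclei the fold of Tmem127 ran from -0.58 to 0.07 and in adipocyte-like nuclei from -0.45 to -0.05. Of the values of named genes, 3358 stayed the same, 176 were stronger and 127 weaker, and of those of lists 182 stayed and 65 were weaker. Where a left-out library leaves 1 KO library, that library is assumed to vary like the other group. No paired analysis was possible because the columns carry no pair numbers and the replicate numbers follow accession order. Depth limits KO replicate 2 most, at a median of 1289 UMIs. DESeq2 gives no list result, and the coarser and finer clusterings do not apply to all nuclei or numbered clusters.

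Counts of genes that edgeR called moved as follows, and the cause was not tested. In all nuclei (0) they were 59 with DESeq2, 358 without the filter on low counts, 7 in annotation B alone, 2 with the newer quasi-dispersion estimate, 8 with it and robust spread, and 6 to 207 with 1 library left out. In chromaffin-like nuclei (0) they were 9 with DESeq2, 101 without the filter, 112 in annotation B alone, 2 with robust spread and 8 to 101 with 1 library left out. In zona fasciculata-like nuclei (0) they were 4 with DESeq2, 40 without the filter, 22 in annotation B alone and 2 to 46 with 1 library left out. In zona glomerulosa-like nuclei (50) they were 0 with the unassigned library as KO, 4 with it as WT, 0 without the batch term, 278 without the filter, 33 with doublets kept, 18 among nuclei with at least 1000 genes and 65 to 116 with 1 library left out; the share that rose was 24 of 50 with edgeR, 13 of 41 with DESeq2 and 18 of 41 with its size factors in edgeR. In the other classes together (50) they were 22 with the unassigned library as KO, 8 as WT, 0 without the batch term, 374 without the filter, 15 with doublets kept, 23 among nuclei with at least 1000 genes, 176 in annotation B alone and 94 to 269 with 1 library left out.

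Counts of lists past the threshold moved too, and the cause was not tested. In all nuclei (5) they were 2 with the unassigned library as WT, 2 to 7 with 1 library left out, and 0 with an estimated correlation and 0 with fry. In chromaffin-like nuclei (5) they were 1 to 7 with 1 library left out and 0 with an estimated correlation or fry. In zona fasciculata-like nuclei (8) they were 5 with the unassigned library as KO, 2 as WT, 4 without the batch term, 5 without the filter, 5 among nuclei with at least 1000 genes, 5 in annotation B alone, 0 to 5 with 1 library left out and 0 with an estimated correlation or fry. In zona glomerulosa-like nuclei (0) they were 2 with the unassigned library as KO, 3 as WT, 2 without the batch term, 2 among nuclei with at least 1000 genes, 1 in annotation B alone, 1 with coarser and 1 with finer clusters and 0 to 5 with 1 library left out.

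With the unassigned library as KO, 47 of 49 measured genes of the 50 called in zona glomerulosa-like nuclei kept their sign, and of the genes named Acvr1c reversed (0.48). Also reversed was, without KO replicate 2, the direction that camera gave to 7 lists. Their medians with 1 library left out, lowest to highest, with the lowest always without KO replicate 2, were these. Interferon response ran from 0.035 to 0.39 in all nuclei and 0.092 to 0.31 in zona fasciculata-like nuclei. Mitochondrial transcripts ran from -0.49 to 1.63 in all nuclei, -0.43 to 2.51 in chromaffin-like and -0.51 to 1.28 in zona fasciculata-like nuclei. In zona fasciculata-like nuclei MAPK output ran from -0.27 to 0.89 and immediate early genes from 0.19 to 1.02. The cause was not tested.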

Other observations

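The tests on clock genes were chosen after the rise of Arntl and Npas2 was seen.

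The values of the unassigned library, left out of the main tests, are these. In its zona glomerulosa-like nuclei Pde10a stood at 1019 CPM, Ppp2r2b at 819, Npr3 at 21.8 and Acvr1c at 86.3, each above the WT mean, and Asic2 at 18.9 and Hsd3b6 at 7.26, each below it. In its chromaffin-like nuclei Th stood at 2699 and Fos at 21.4, and the summed immediate early and heat shock genes at 848. That sum was 3615 in its zona fasciculata-like nuclei, 2725 in its zona glomerulosa-like nuclei and 1973 in all its nuclei, against 278 to 378 in all nuclei of the WT libraries. Its share of chromaffin-like nuclei was 7.09%.

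KO replicate 2 differed from the other libraries in 1 further way. Erythroid transcripts, of red blood cells, stood at 74.1 CPM in all its nuclei, against 4.86 in KO replicate 1 and 5.30 to 13.1 in WT.

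A hypothesis for the rise of the clock genes Arntl (fold 1.42 ± 0.25) and Npas2 (2.91 ± 0.45) in zona glomerulosa-like nuclei is that KO and WT glands were collected at another clock phase. The 10 clock genes of the opposite phase had a median fold of -0.42 ± 0.15 (SE) there, 9 of them below 0. That met the mark set for a differing phase. The 5 clock genes that peak with Arntl had a median of 0.19 ± 0.92, 2 of them below 0. The median fold of Arntl over 9 other classes was -0.046 ± 0.41, too uncertain to meet either mark set for a shift of every class. Together these values do not decide whether the phase differed. Elsewhere the median of the opposite-phase genes measured was below 0 in endothelial-like (-0.22 ± 0.17), capsule or fibroblast-like (-0.05 ± 0.09) and cluster 7 nuclei (-0.06 ± 0.22). In the other classes it was above 0, among them chromaffin-like (0.16 ± 0.13) and zona fasciculata-like nuclei (0.0054 ± 0.25). A second hypothesis, an effect in zona glomerulosa-like nuclei alone, was not decided either: Arntl and Npas2 had a median fold of -0.044 over the other classes. The difference in genotype effect between zona glomerulosa-like and zona fasciculata-like nuclei did not pass for either gene (Arntl 1.38 ± 0.37, Npas2 2.56 ± 0.67, adjusted p = 1.00 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Collection times are not given in the labels.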
